A study of Mus musculus with 20 samples.

How the data were processed

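RNA was measured by sequencing in 20 libraries of mouse bone marrow-derived macrophages, from 5 mice under each of 4 culture conditions. Per the labels, the cells grew in DMEM with Glutamax, serum and conditioned medium of L929 cells, a fibroblast line whose medium supplies the macrophage growth factor CSF-1, and were then treated for 48 h with different formulations. The conditions are named as the labels give them: LP, LP PIC, LP 3M and LP 3M PIC. LP was read as the lipoparticle of the series title, LP PIC and LP 3M as the single formulations and LP 3M PIC as the dual one. What the codes PIC and 3M stand for was not taken from outside the labels. RNA was extracted with a NucleoSpin kit and made into stranded, poly(A)-enriched libraries.

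The deposited values are raw counts of reads per gene symbol, whole numbers that the authors had not normalised, in 1 table per library. The submitters' processing notes name FastQC 0.11.1, STAR 2.7.11b, HTSeq 0.13.5 and DESeq2 1.44.0 with genome build GRCm38. The annotation and the strand setting used for counting are not given in the sources used here. Each table lists 24421 genes and 5 entries that belong to no gene, of which 3 were at 0 in every library. Reads outside annotated genes made up 5.94 to 8.58% and reads shared by more than 1 gene 1.14 to 1.90%, and these entries stayed out of library sizes and tests. Coordinates come from GENCODE M21 on GRCm38, in which 23376 of the symbols (95.7%) were found.

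Total gene counts ran from 9740528 to 23874805 per library with a median of 22751911, so that a floor of 3 counts corresponds to between 0.126 and 0.308 CPM (a gene's count scaled to a fixed library size). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries held duplicate counts: over all 190 pairs the chi-squared per degree of freedom ran from 7.74 to 567, with the lowest within a condition.

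Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12132 genes holding 99.969% of the counts. Libraries were scaled by TMM, with factors from 0.945 to 1.07. CPM of single genes use these scaled library sizes, and sums over cell type markers use the plain library totals. The edgeR quasi-likelihood F-test, two-sided, was run with robust dispersion on 1 model with a mean per condition over all 20 libraries, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called. The biological coefficient of variation was 0.194. The 7 contrasts were each formulation against LP, the dual formulation against each single one, LP 3M against LP PIC, and the interaction, which is the difference between LP 3M PIC and LP 3M minus the difference between LP PIC and LP on the log2 scale. Comparisons of the dual with a single formulation, the interaction and sums of single effects assume equal amounts of each adjuvant in both. The sample information used here holds no amounts, so this could not be checked. Errors of log2 fold changes are the SE implied by the F-test, the absolute log2 change divided by the square root of F. For genes with few counts this implied SE is only a rough guide. Errors of CPM are the SD over 5 mice.

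Comparisons, tests, alternatives, gene lists and the rule for naming genes were written before the data were examined. For each contrast, the rule names the 6 genes with the largest rise and the 6 with the largest fall among called genes with at least 5 CPM in the higher condition and the same direction in 5 of 5 mice, without unnamed gene models. It adds, for each described list, the 3 tested members with the smallest p and the called member with the smallest p against the list's direction. A panel of 28 immune genes is added, with Acod1 under the older symbol Irg1. For marker and quality lists, up to 3 members with the highest CPM are named. The 22 gene lists covered interferon-stimulated antiviral genes, interferon-gamma-type GTPases, interferon ligands, inflammatory cytokines, chemokines, NF-kB regulators and targets, MHC class I, MHC class II, costimulation and checkpoint ligands, pattern recognition receptors, inflammasome and lytic cell death, classical activation enzymes, alternative activation, macrophage identity, cholesterol synthesis, LXR targets and lipid handling, glycolysis, oxidative phosphorylation, proliferation, NRF2 and heme response, the unfolded protein and integrated stress response, and lysosome. Of 605 list members, 604 were in the tables, including 2 under an older symbol. Lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment within each contrast. Of the 22 lists 21 were tested, since 1 member of the interferon ligands, Ifnb1, passed the filter. Markers of 12 other cell types and 3 quality lists (mitochondrially encoded, immediate early and replication-dependent histone genes) were summed as levels.

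The labels give the same 5 mouse identifiers in every condition, so that libraries with the same number come from the same animal. Deviations from the condition means correlated between libraries of the same mouse at r = 0.137 to 0.541, and 19 of the 20 libraries correlated best with their own mouse. The test used no block for mouse, and the block was an alternative (residual degrees of freedom 12 in place of 16, biological coefficient of variation 0.136). The other alternatives were median-ratio size factors (RLE), no filter on low counts, the DESeq2 Wald test, a fit to the libraries of the 2 compared conditions alone, each library and each mouse left out in turn, and for lists camera with an estimated correlation and fry. For the comparison of the single responses, the LP libraries were also split between the contrasts. Chosen after the data had been seen were fits to mice 1 and 2 alone and to mice 3 to 5 alone, a fit without the 2 shallowest libraries, and a test of additivity on the CPM scale.

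The pipeline was tested on simulated data with the depth and spread of these libraries. Of 12022 simulated genes 239 were changed, all in LP PIC, and libraries were drawn without a mouse effect. The rates therefore do not cover comparisons in which as many genes move as in the data. In the simulated comparison of LP PIC with LP, 2.5% of the calls were false, and 50% of true changes of 0.5, 79.1% of 1 and 95.5% of 2 on the log2 scale were recovered. For the interaction, where the change in LP PIC was the only simulated one, 4.17% of simulated calls were false. Genes with paralogs of near-identical sequence, such as the Ifit3, Gbp, Apol9, Oas1, Bcl2a1, Tgtp and H2-Q families, carry the uncertainty of reads that could map to several of them. A gene at 0 in every library of a condition is given as a lower bound against 3 counts over the condition, and a gene with 1 to 3 counts as a ratio with a 95% counting interval. Protein, secretion and cell counts were not analysed here.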

Results

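Macrophages grown from the bone marrow of 5 mice were exposed for 48 h to a lipoparticle alone (LP), to 1 of 2 single adjuvant formulations on it (LP PIC and LP 3M) or to the dual formulation that carries both (LP 3M PIC). RNA of each mouse was sequenced under each condition, which gave 20 libraries, 5 per condition. Depth, in M (mega) counts, was 20.4 ± 5.96 in LP, 21.9 ± 2.58 in LP PIC, 22.6 ± 0.848 in LP 3M and 20.0 ± 4.53 in LP 3M PIC (mean and SD, n = 5). The lowest totals were 9.74 M in LP of mouse 2, 12.5 M in LP 3M PIC of mouse 3 and 17.4 M in LP PIC of mouse 5, and the other 17 lay between 19.1 and 23.87 M. Between 13593 and 14680 genes were detected per library. The comparisons ask what each single formulation changed in the macrophages, what the dual one changed, and whether it did more or less than the single ones added together.

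The libraries separated by condition. Over the 1000 most variable genes, the first principal component held 59.2% and the second 20.6% of the variance. Against LP, edgeR's quasi-likelihood test called 5515 genes for LP PIC (2758 higher, 2757 lower), 4790 for LP 3M (2422 higher, 2368 lower) and 7551 for the dual formulation (3840 higher, 3711 lower). The calls with a change of at least 1 on the log2 scale were 1584, 1165 and 2676. Each gene written as risen or fallen was called at a Benjamini-Hochberg adjusted p under 0.05 and moved that way in 5 of 5 mice unless another number is given. Changes are log2 fold changes with the SE implied by the test, n = 5 per condition.

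**Figure D1:**
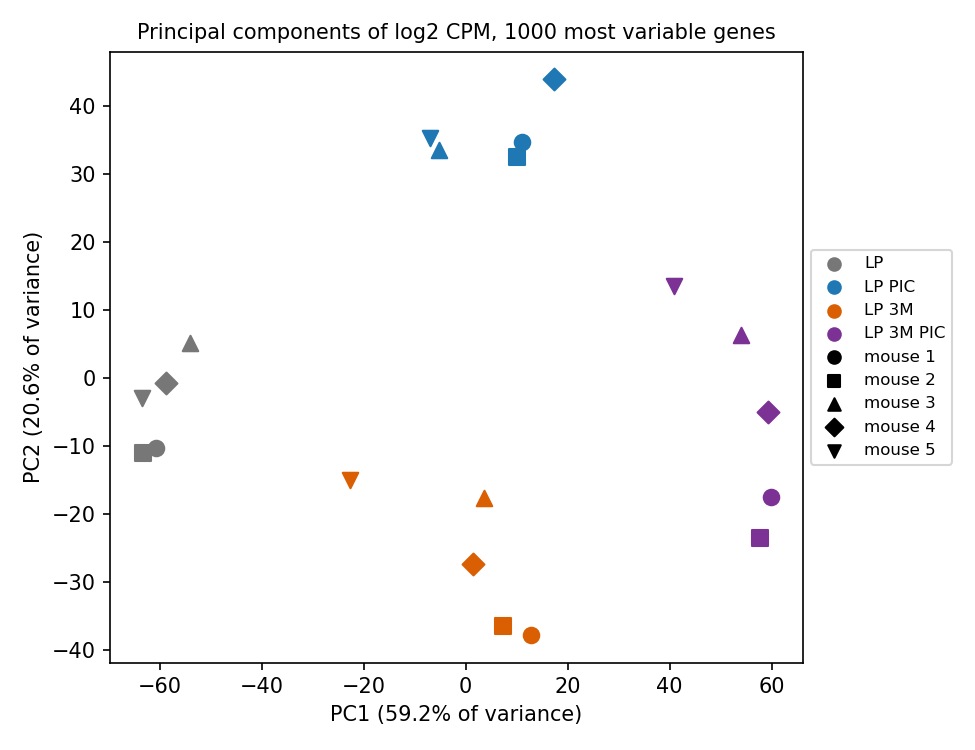
Principal components of log2 CPM over the 1000 most variable genes, with the first component (59.2% of the variance) on the x axis and the second (20.6%) on the y axis. Each point is 1 library, coloured by condition and shaped by mouse, and the 4 conditions occupy separate areas.

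**Figure D2:**
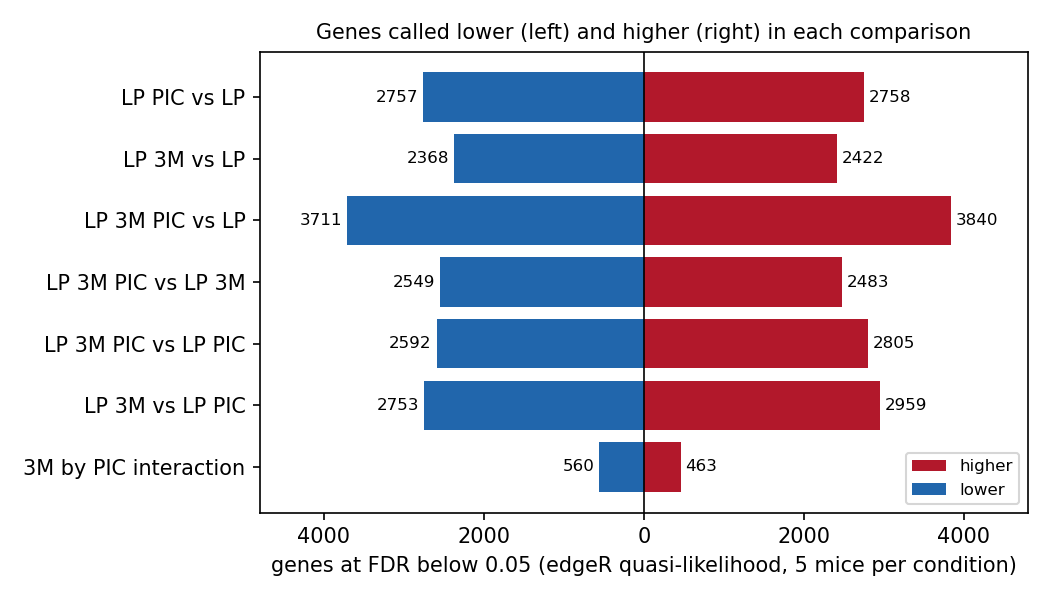
Number of genes called at an adjusted p under 0.05 by edgeR's quasi-likelihood test, lower to the left and higher to the right, for the 6 comparisons and the interaction. The dual formulation against LP gave the longest bar (3840 higher, 3711 lower) and the interaction the shortest (463 higher, 560 lower).

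The first question was what LP PIC changed relative to the lipoparticle alone. Nos2, the inducible nitric oxide synthase, rose by 8.77 ± 0.89 (0.208 CPM in LP, 92.9 ± 59.8 in LP PIC, adjusted p = 3.06e-07). H2-M2, a non-classical MHC class I gene, rose by 7.87 ± 0.55 (6.45 to 1512 ± 623 CPM, adjusted p = 6.76e-09). Cxcl10, a chemokine that recruits activated T cells, rose by 6.52 ± 0.53 (1.13 to 102 CPM, adjusted p = 2e-08) and Ccl5, another T cell chemokine, by 4.28 ± 0.56 to 4779 CPM. Krt16, a keratin, and Cxcl11, a further ligand of the receptor for Cxcl10, had no counts in LP and were at least 496-fold and at least 295-fold higher in LP PIC. Rasgrp1, an activator of Ras, rose by 7.51 ± 0.69 and the interferon-inducible Ifit1bl1 by 7.47 ± 0.96. The largest falls were those of Nes, an intermediate filament gene (−4.94 ± 0.44), Nptx1 (−4.58 ± 0.39), the calcium pump gene Atp2b4 (−4.49 ± 0.56), Nanos1 (−4.34 ± 0.36), and Depdc1b (−4.22 ± 0.34) and Ccnb2 (−4.18 ± 0.30), both genes of cell division.

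Of 45 interferon-stimulated antiviral genes 43 rose with LP PIC, and all 45 did when adjusted over the list alone (median log2 change 1.80). Isg15, a ubiquitin-like antiviral modifier, rose by 3.63 ± 0.56 and Phf11d by 3.02 ± 0.33, and the list test gave an adjusted p = 4.26e-18 (adjusted p = 0.206 with an estimated correlation). Ifnb1, the interferon beta gene, was the 1 tested interferon ligand and went from 0.00829 to 1.08 CPM, a ratio of 116 with a counting interval of 20.8 to 4580. Of 19 interferon-gamma-type GTPases 18 rose, Gbp6 by 4.51 ± 0.38 (list median 2.15, adjusted p = 8.27e-12, adjusted p = 0.109 with an estimated correlation). Of 21 MHC class I genes 19 rose, among them H2-K1 by 2.08 ± 0.20 (adjusted p = 1.13e-13, adjusted p = 0.102 with an estimated correlation). Of 13 MHC class II genes 10 rose, among them H2-Ab1 by 4.27 ± 0.41, and Ciita, the master regulator of class II, rose by 4.06 ± 0.54 (adjusted p = 1.46e-06 for the list, adjusted p = 0.11 with an estimated correlation). Costimulation and checkpoint ligands rose in 15 of 23 cases and fell in 3 (median 0.85, adjusted p = 0.000127, adjusted p = 0.102 with an estimated correlation), with Cd86 up by 2.29 ± 0.22 and Cd274, which encodes PD-L1, by 2.53 ± 0.23.

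NF-kB regulators and targets rose in 25 of 30 cases with LP PIC (26 adjusted over the list alone; median 1.45, adjusted p = 1.65e-22). Relb, an NF-kB subunit, rose by 1.77 ± 0.10, and Sod2, the mitochondrial superoxide dismutase, by 3.01 ± 0.17. Of 20 classical activation enzymes 17 rose (median 3.59, adjusted p = 4.04e-16), among them Arg2, a mitochondrial arginase, by 3.93 ± 0.26 and Irg1, the itaconate-producing enzyme, by 4.34 ± 0.38. Inflammatory cytokines rose in 12 of 20 cases (median 1.74, or 1.60 with genes without counts at their bound; adjusted p = 0.000106, adjusted p = 0.185 with an estimated correlation). Tnf rose by 1.70 ± 0.19 and Il1b by 3.55 ± 1.09 (adjusted p = 0.0122). Il12b rose by 4.84 ± 1.36 to 1.22 CPM (adjusted p = 0.00721), a call lost without mouse 4 (adjusted p = 6.68e-06 to 0.0618 over the alternatives, highest without mouse 4). Il6 was not called at 0.642 CPM (3.93 ± 1.99, adjusted p = 0.117), but was with mouse as a block (adjusted p = 0.0268; 0.00053 to 0.209 over the alternatives). Chemokines rose in 8 of 23 cases and fell in 2, among them Cx3cl1 with a log2 change of −1.47 (list median 1.78, adjusted p = 0.00184, adjusted p = 0.258 with an estimated correlation). Ccl2, a monocyte chemokine, stood at 96.6 CPM in LP and 50.7 in LP PIC (adjusted p = 0.102, and 0.00274 with mouse as a block; 0.00274 to 0.232 over the alternatives). Pattern recognition receptors rose in 23 of 35 cases, Clec4e by 4.95 ± 0.32 and Tlr2 by 2.73 ± 0.22 (adjusted p = 1.46e-06, adjusted p = 0.102 with an estimated correlation). Inflammasome and lytic cell death genes rose in 14 of 20 cases, with Gsdmd, the pore-forming effector of pyroptosis, up by 1.22 ± 0.15 (adjusted p = 1.18e-05).

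Proliferation genes fell with LP PIC in 39 of 40 cases, with a median of −2.66 (adjusted p = 7.81e-59). Plk1, a mitotic kinase, fell by 3.59 ± 0.25 and Mcm6, a subunit of the replicative helicase, by 1.65 ± 0.12. Oxidative phosphorylation genes rose in 17 of 34 cases and fell in 2, by small amounts (median 0.20, adjusted p = 0.00697, adjusted p = 0.595 with an estimated correlation). Alternative activation genes fell in 8 of 17 cases and rose in 1 (median −0.65, adjusted p = 0.0991). They passed with mouse as a block (adjusted p = 0.035; 0.035 to 0.136 over the alternatives other than an estimated correlation and fry) and by fry (adjusted p = 0.000768). The tests of macrophage identity, cholesterol synthesis, LXR targets, glycolysis, the NRF2 and stress responses and lysosome gave adjusted p from 0.185 to 0.904, although cholesterol synthesis passed without mouse 5 (adjusted p = 0.0279; 0.0279 to 0.332 over the alternatives other than an estimated correlation and fry). Of these, NRF2 genes had a median of −0.20 but a mean of 0.18 and an upward test, and identity (median 0.01, mean −0.13) and glycolysis (median 0.00, mean 0.01) a downward one. The calls for NF-kB, inflammasome, classical activation and proliferation held with an estimated correlation (adjusted p = 0.0157, 0.0458, 0.0157 and 0.0165), and the other 9 of the 13 list calls did not.

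LP 3M was compared with LP to ask what the other single formulation changed. Fpr1 and Fpr2, receptors for formylated bacterial peptides, rose by 9.06 ± 0.53 (0.253 to 148 ± 38.9 CPM, adjusted p = 6.39e-10) and 8.75 ± 0.67 (0.154 to 71.4 CPM). Cxcl3, a neutrophil chemokine, rose by 9.67 ± 1.34 (0.0622 to 51.0 ± 59 CPM, adjusted p = 2.08e-05) and the NAD-consuming ectoenzyme gene Cd38 by 8.56 ± 1.15. Nhs had no counts in LP and was at least 203-fold higher, and Lad1 had a ratio of 591 with a counting interval of 106 to 23400. Shisa9 (−4.30 ± 0.47), Pgm5 (−3.50 ± 0.41), Tox2 (−3.46 ± 0.48), Flt1, a VEGF receptor gene (−3.39 ± 0.67), and Lrrc14b (−3.24 ± 0.54) fell most. Cd34, a progenitor marker, fell by 3.08 ± 0.88 (adjusted p = 0.00984), a call lost without mouse 4 (adjusted p = 0.059; 4.37e-06 to 0.059 over the alternatives).

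NF-kB regulators and targets rose with LP 3M in 26 of 30 cases (median 1.49, adjusted p = 6.01e-35) and classical activation enzymes in 17 of 20 (18 adjusted over the list alone; median 4.00, adjusted p = 2.37e-23). Sod2 rose by 3.89 ± 0.18 and Zc3h12a, an RNase that limits cytokine transcripts, by 2.74 ± 0.16, while Irg1 rose by 5.11 ± 0.39 and Nos2 by 6.47 ± 0.90 to 18.9 CPM. These were the 2 list calls of LP 3M against LP that held with an estimated correlation (adjusted p = 0.00198 for each). Cytokines rose in 12 of 20 cases and fell in 2 (13 rose adjusted over the list alone; median 2.16, adjusted p = 5.88e-06, adjusted p = 0.224 with an estimated correlation). Tnf rose by 3.62 ± 0.21 (33.2 to 410 CPM, adjusted p = 2.67e-10) and Il6 by 8.55 ± 1.25 (0.0341 to 16.3 CPM, adjusted p = 3.55e-05). Il1b rose by 8.16 ± 1.11 to 128 CPM and Il12b by 5.48 ± 1.26 to 1.95 CPM, while Il18 fell by 1.21. Chemokines rose in 13 of 23 cases, Cxcl2 by 5.93 ± 0.51 and Cxcl1 by 6.40 ± 0.67 (adjusted p = 5.17e-05, adjusted p = 0.224 with an estimated correlation), and Ccl2 rose by 2.09 ± 0.46. Neutrophil marker genes summed to 13.4 CPM in LP and 343 in LP 3M, mostly Lcn2, a siderophore-binding protein gene. LP 3M of mouse 5 stood apart from the other mice, with Il1b at 3.59 CPM against 73.5 to 328 and Il6 at 0.437 against 6.78 to 39.1, while its Tnf, at 308 CPM, lay within their 283 to 550.

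Of 45 antiviral genes 3 rose with LP 3M, or 1 adjusted over the list alone (median 0.37, adjusted p = 0.113, adjusted p = 0.795 with an estimated correlation). Isg15 stood at 59.3 CPM against 23.8 in LP (1.31 ± 0.52, adjusted p = 0.0528), and passed with mouse as a block (adjusted p = 0.00389; 0.00389 to 0.137 over the alternatives). The same held for Cxcl10 at 2.27 CPM (adjusted p = 0.164, and 0.0412 with the block; 0.0412 to 0.367 over the alternatives). Ifnb1 was at 0 in LP 3M and at 0.00829 CPM in LP, both under the floor of 3 counts. GTPases rose in 7 of 19 cases (median 0.43, adjusted p = 0.0395, adjusted p = 0.584 with an estimated correlation). MHC class I genes rose in 7 of 21 cases (median 0.31, adjusted p = 0.0409, adjusted p = 0.584 with an estimated correlation); this call was lost without mouse 1 (adjusted p = 0.0517) and without mouse 5 (adjusted p = 0.0761). MHC class II genes rose in 5 of 13 cases and fell in 2 (median 1.02, adjusted p = 0.107). This list passed without mouse 2 (adjusted p = 0.042; 0.042 to 0.175 over the alternatives other than an estimated correlation and fry) and, at just under 0.05, without mouse 3. It also passed by fry (adjusted p = 0.0408), which GTPases and MHC class I did not (adjusted p = 0.0577 each). Costimulation and checkpoint ligands rose in 9 of 23 cases and fell in 2 (median 0.32, adjusted p = 0.0231, adjusted p = 0.366 with an estimated correlation), with Cd40, a costimulatory receptor, up by 2.19 ± 0.41. Pattern recognition receptors rose in 18 of 35 cases and fell in 6, with Irak3, an inhibitor of Toll-like receptor signalling, up by 3.10 ± 0.15 (adjusted p = 3.16e-06, adjusted p = 0.224 with an estimated correlation). Inflammasome genes rose in 11 of 20 cases and fell in 4, with Nlrp3 up by 1.73 ± 0.12 (adjusted p = 0.011, adjusted p = 0.224 with an estimated correlation).

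Glycolysis genes rose with LP 3M in 12 of 25 cases and fell in 3, with Hif1a, the hypoxia-response regulator, up by 1.10 ± 0.10 (list median 0.39, adjusted p = 0.000647, adjusted p = 0.315 with an estimated correlation). NRF2 and heme response genes rose in 14 of 23 cases, with the cystine transporter gene Slc7a11 up by 4.06 ± 0.32 (median 0.49, adjusted p = 4.84e-05, adjusted p = 0.224 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 25 cases (12 adjusted over the list alone; median 0.36, adjusted p = 0.02, adjusted p = 0.584 with an estimated correlation). Stress response genes rose in 11 of 26 cases and fell in 3, with Herpud1 up by 1.14 (adjusted p = 0.019, adjusted p = 0.475 with an estimated correlation). Oxidative phosphorylation genes rose in 11 of 34 (median 0.14, adjusted p = 0.00574, adjusted p = 0.553 with an estimated correlation). Proliferation genes fell in 25 of 40 cases with a smaller median of −0.57 (adjusted p = 7.22e-06, adjusted p = 0.475 with an estimated correlation), among them Pcna by 0.90 ± 0.12. Alternative activation, macrophage identity, LXR targets and lysosome gave adjusted p from 0.113 to 0.498. By fry, alternative activation (adjusted p = 0.0115) and LXR targets (adjusted p = 0.00416) passed downward. Identity genes had a median of −0.04 but a mean of 0.08, with Adgre1, which encodes the F4/80 antigen, up by 2.64 ± 0.22. Abcg1, a cholesterol exporter among the LXR targets, fell by 1.38 ± 0.09.

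The dual formulation was compared with LP to ask what both adjuvants changed together. Il12b, which encodes the shared subunit of interleukins 12 and 23, rose by 12.99 ± 0.91 (0.0343 to 353 ± 190 CPM, adjusted p = 1.3e-09) and Il6 by 12.56 ± 1.16 (0.0341 to 262 ± 121 CPM, adjusted p = 3.79e-08). Il1b rose by 11.20 ± 1.20 to 1055 CPM, Nos2 by 10.19 ± 0.91 to 249 CPM and Serpinb2, an inhibitor of plasminogen activators, by 11.82 ± 1.83 to 974 ± 1160 CPM. Cxcl3 rose by 11.48 ± 1.32, and U90926 and Lad1 had ratios of 5490 (counting interval 1880 to 26600) and 3770 (677 to 149000). U90926 varied widely between mice, at 151 ± 207 CPM in LP 3M PIC, with log2 differences from 4.88 in mouse 5 to 12.37 in mouse 2. The largest falls were those of Mamdc2 (−8.92 ± 0.89, 57.8 ± 4.52 to 0.115 CPM), Pgm5 (−7.20 ± 0.58), Tox2 (−6.61 ± 0.63), Cd34 (−6.22 ± 1.16), Pcp4l1 (−6.09 ± 0.35) and Nes (−6.00 ± 0.48). Mrc1, the mannose receptor of alternatively activated macrophages, fell by 3.40 ± 0.61 and Csf1r, the CSF-1 receptor, by 0.42 ± 0.11.

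**Figure D3:**
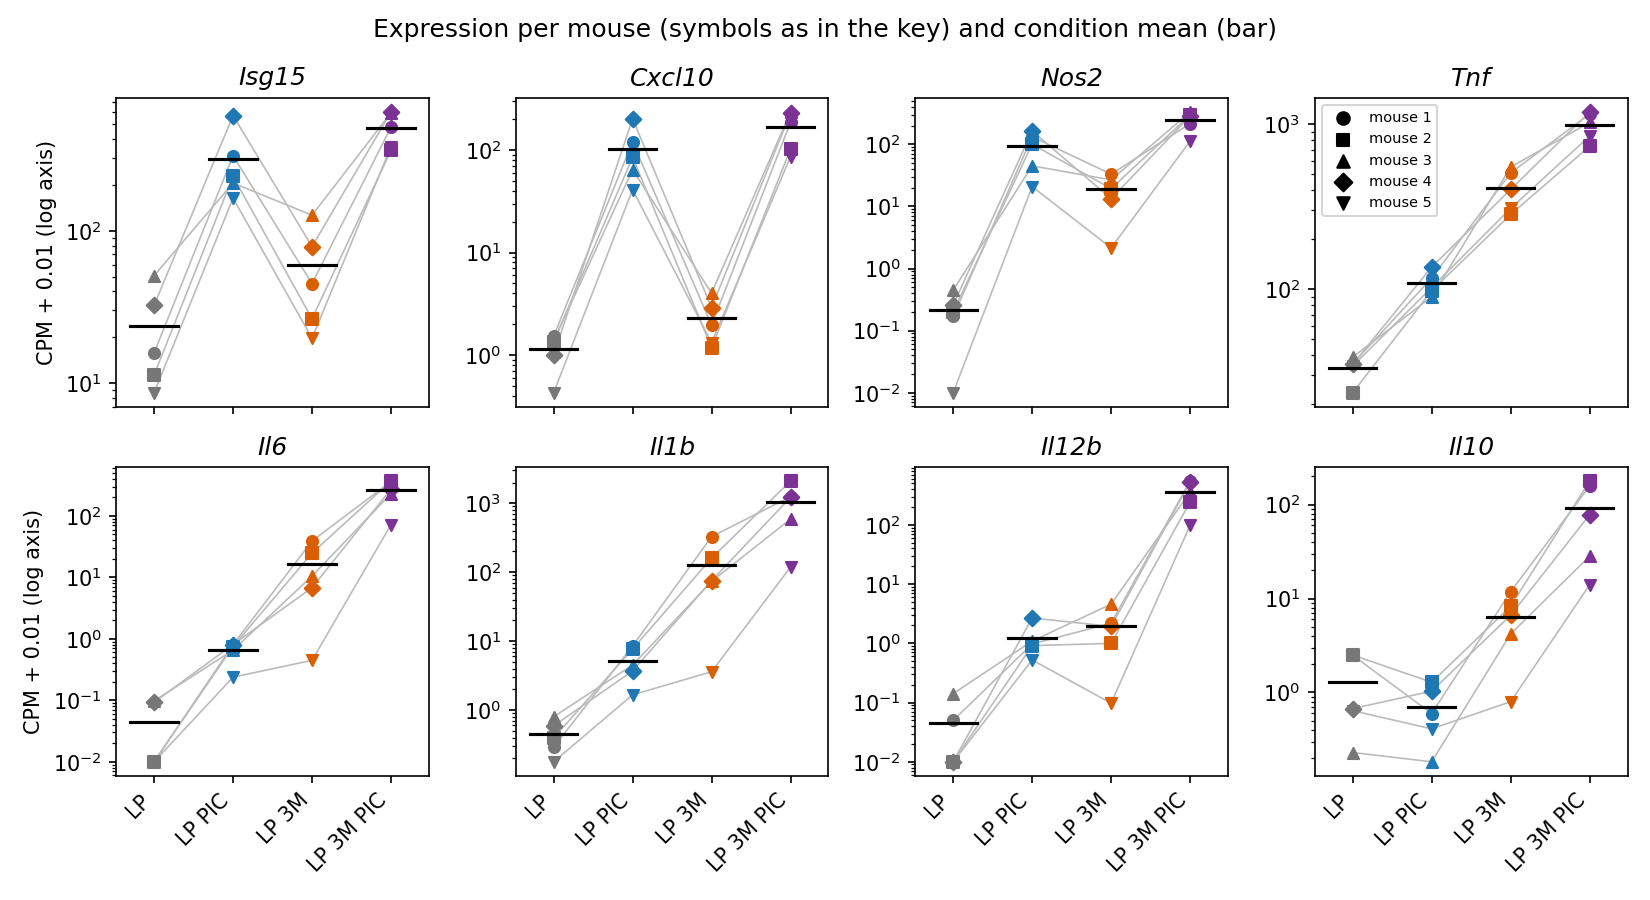
CPM plus 0.01 on a log axis for 8 genes under the 4 conditions on the x axis. Points are the 5 mice, grey lines join libraries of the same mouse and black bars are condition means; Il12b reached 353 CPM in LP 3M PIC against 1.22 in LP PIC and 1.95 in LP 3M, while Isg15 reached 474 against 295.7 and 59.3 CPM.

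Of 20 cytokine genes 18 rose with the dual formulation (median 5.09, adjusted p = 1.91e-09, adjusted p = 0.109 with an estimated correlation). Tnf rose by 4.89 ± 0.22 (33.2 to 990 CPM), the anti-inflammatory Il10 by 6.24 ± 0.82 (1.30 to 91.1 CPM) and Il27 by 5.25 ± 0.54. Neutrophil marker genes summed to 1519 CPM, against 13.4 in LP. Of 30 NF-kB genes all 30 rose (median 2.27, adjusted p = 5.56e-32) and of 20 classical activation enzymes 19 rose (20 adjusted over the list alone; median 5.74, adjusted p = 1.46e-17). These were the 2 of 18 list calls that held with an estimated correlation (adjusted p = 0.00542 and 0.00632). Chemokines rose in 17 of 23 cases and fell in 2 (adjusted p = 6.38e-06, adjusted p = 0.111 with an estimated correlation). Antiviral genes rose in 44 of 45 cases, Isg15 by 4.31 ± 0.58 and Oasl1 by 5.16 ± 0.57 (median 2.02, adjusted p = 1.13e-10, adjusted p = 0.303 with an estimated correlation). GTPases rose in 17 of 19 (adjusted p = 1.73e-07, adjusted p = 0.205 with an estimated correlation). MHC class I genes rose in 20 of 21 (adjusted p = 5.05e-07, adjusted p = 0.222 with an estimated correlation). MHC class II genes rose in 11 of 13 (adjusted p = 0.00152, adjusted p = 0.279 with an estimated correlation). Ifnb1 reached 2.698 CPM, a ratio of 288 with a counting interval of 51.7 to 11400. Costimulation and checkpoint ligands rose in 15 of 23 cases and fell in 6, Cd40 rising by 5.57 ± 0.46 and Havcr2, which encodes the checkpoint receptor TIM-3, falling by 2.45 (adjusted p = 0.000424, adjusted p = 0.109 with an estimated correlation). Pattern recognition receptors rose in 22 of 35 and fell in 6 (adjusted p = 9.61e-07, adjusted p = 0.109 with an estimated correlation). Inflammasome genes rose in 13 of 20 and fell in 3, Nlrp3 rising by 2.85 ± 0.12 and Nlrp1b falling by 3.82 (adjusted p = 0.000786, adjusted p = 0.109 with an estimated correlation).

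Proliferation genes fell with the dual formulation in 37 of 40 cases (median −2.18, adjusted p = 8.69e-24, adjusted p = 0.109 with an estimated correlation), Ccnd1, a G1 cyclin, by 4.62 ± 0.29. Alternative activation genes fell in 9 of 17 and rose in 3, with the growth factor gene Igf1 down by 3.83 ± 0.26 and Pparg, a lipid-sensing nuclear receptor, by 2.16 ± 0.15 (median −0.95, adjusted p = 0.0342, adjusted p = 0.279 with an estimated correlation). LXR targets and lipid handling genes fell in 15 of 26 and rose in 3, with the lipoprotein lipase gene Lpl down by 4.15 ± 0.36 (adjusted p = 0.0342, adjusted p = 0.205 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 25 and rose in 2, with Dhcr7 down by 2.02 ± 0.18 (adjusted p = 0.0483, adjusted p = 0.592 with an estimated correlation). This list call was lost without mouse 1, 2 or 3 (adjusted p = 0.0765, 0.0777 and 0.0689). Lysosome genes fell in 19 of 35 and rose in 8, with the cathepsin gene Ctsb down by 0.98 ± 0.10 and Ctsc up by 2.56 (adjusted p = 0.0483, adjusted p = 0.529 with an estimated correlation). That call was lost without mouse 1, 3 or 4 (adjusted p = 0.0506, 0.0963 and 0.0746). NRF2 genes rose in 13 of 23 and fell in 6 (adjusted p = 0.00394, adjusted p = 0.297 with an estimated correlation). Stress response genes rose in 15 of 26 and fell in 4 (adjusted p = 0.0223, adjusted p = 0.36 with an estimated correlation). Glycolysis and oxidative phosphorylation (adjusted p = 0.124 each) and macrophage identity (adjusted p = 0.351) did not pass. By fry they did, the first 2 upward (adjusted p = 0.00239 and 0.0162) and identity downward (adjusted p = 0.0131).

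**Figure D4:**
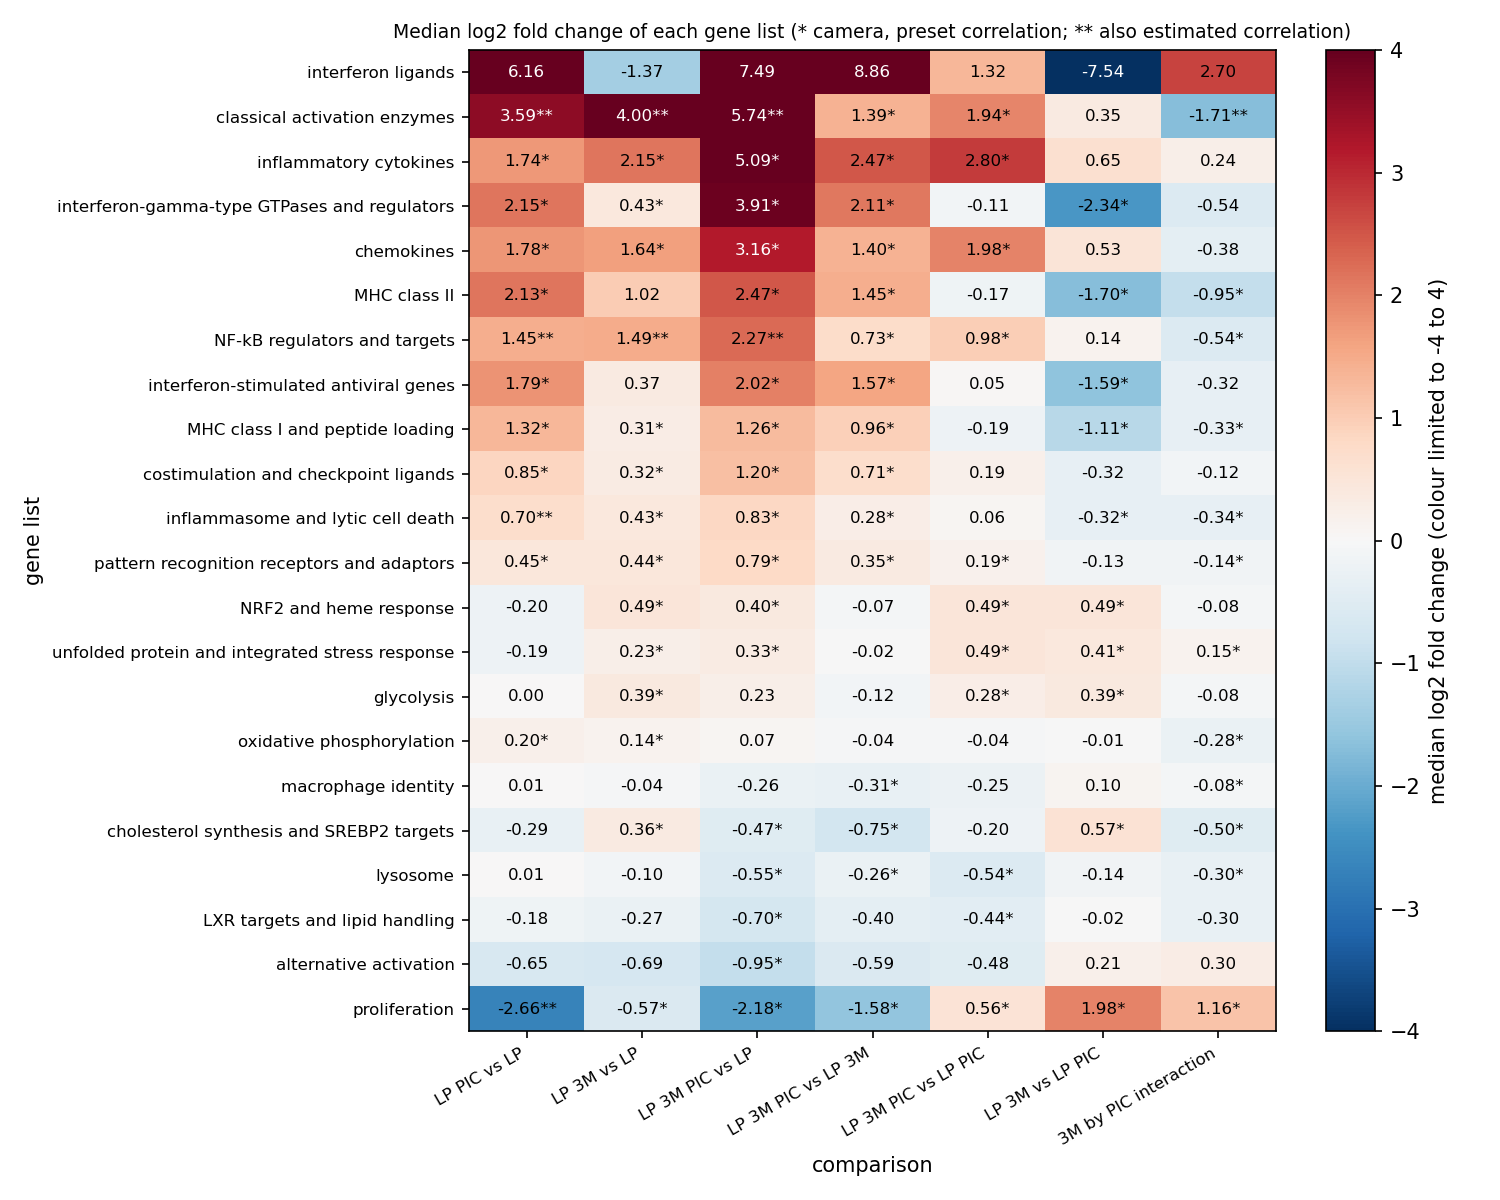
Median log2 fold change of the tested members of each gene list (y axis) in each comparison (x axis), with 1 asterisk where camera passed at its preset correlation and 2 where it also passed with an estimated correlation. Among the 21 lists with more than 1 tested member, classical activation and cytokine genes had the highest medians in the dual formulation against LP (5.74 and 5.09), and proliferation the lowest (−2.18).

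The dual formulation was set against LP 3M to ask what adding PIC did, and 5032 genes were called (2483 higher, 2549 lower). Cxcl10 rose by 6.21 ± 0.50 (2.27 to 167 ± 69.8 CPM, adjusted p = 2.46e-07) and Il12b by 7.51 ± 0.61 (adjusted p = 2.92e-07). Ccr7, a homing receptor of activated antigen-presenting cells, rose by 6.56 ± 0.75 and the lipase gene Lipg by 7.24 ± 1.15. Krt16 and Dnase1l3, a secreted DNase gene, had ratios of 499 (counting interval 138 to 4120) and 576 (103 to 22800), and Ifnb1 was at least 106-fold higher. Mamdc2 (−6.35 ± 0.92), Mmp12, the macrophage elastase gene (−3.87 ± 0.55, 2004 ± 366 to 137 CPM), Nes (−3.70), the fractalkine receptor gene Cx3cr1 (−3.50 ± 0.88), Pcp4l1 (−3.38 ± 0.34) and Serinc2 (−3.12) fell most. Antiviral genes rose in 43 of 45 cases (44 adjusted over the list alone; median 1.57, adjusted p = 6.2e-20, adjusted p = 0.174 with an estimated correlation), with Isg15 up by 3.00 ± 0.54. GTPases rose in 18 of 19 (adjusted p = 2.67e-12, adjusted p = 0.128 with an estimated correlation). Cytokines rose in 17 of 20 (18 adjusted over the list alone; adjusted p = 1.96e-10, adjusted p = 0.0814 with an estimated correlation), with Il27 up by 4.39 and Il10 by 3.85 ± 0.69. Cholesterol synthesis genes fell in 22 of 25 cases (median −0.75, adjusted p = 1.29e-08, adjusted p = 0.174 with an estimated correlation), Dhcr7 by 1.58 ± 0.17, while Ggps1 rose by 0.56. Proliferation genes fell in 37 of 40 (median −1.58, adjusted p = 5.44e-34, adjusted p = 0.0814 with an estimated correlation), Mcm2 by 1.68 ± 0.14. The other lists that passed at the preset correlation were NF-kB, chemokines, both MHC lists, costimulation, pattern recognition, inflammasome, classical activation, lysosome and identity; the last was lost without mouse 3 (adjusted p = 0.0572). None of the 15 held with an estimated correlation, and the lowest adjusted p was 0.0814.

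To ask what adding 3M did, the dual formulation was set against LP PIC, and 5397 genes were called (2805 higher, 2592 lower). Csf3, the gene of the granulocyte growth factor G-CSF, had a ratio of 4510 (counting interval 810 to 178000), and Nhs and Lum, which encodes a matrix proteoglycan, were at least 468-fold and at least 441-fold higher. U90926 rose by 9.83 ± 1.68, Il6 by 8.62 ± 0.86 (adjusted p = 8.41e-07), Il12b by 8.15 ± 0.64 and Il10 by 7.01 ± 0.87, and Draxin had a ratio of 494 (137 to 4080). The kinase gene Matk (−3.91 ± 0.47), Rgs2, a brake on G-protein signalling (−3.24 ± 0.31, 104 to 11.03 CPM), Fam198b (−3.12 ± 0.33), Zfp395 (−2.98 ± 0.27) and Rapgef3 (−2.92 ± 0.46) fell. So did Cspg4 (−3.14), whose call was lost without mouse 3 (adjusted p = 0.0891; 0.000103 to 0.0891 over the alternatives). Cytokines rose in 14 of 20 cases and fell in 2 (15 rose adjusted over the list alone; median 2.80, adjusted p = 2.56e-09, adjusted p = 0.0908 with an estimated correlation), with Tnf up by 3.19 ± 0.20. Chemokines rose in 12 of 23 and fell in 2, Cxcl1 by 6.02 and Ccl3 by 3.93 (adjusted p = 0.000152, adjusted p = 0.227 with an estimated correlation). NF-kB genes rose in 24 of 30 (adjusted p = 1.74e-15) and classical activation enzymes in 17 of 20 (adjusted p = 1.45e-08), with an adjusted p = 0.0908 for each with an estimated correlation. The antiviral list had a median of 0.05 and a mean of −0.02 (adjusted p = 0.859, adjusted p = 0.974 with an estimated correlation), and Isg15 changed by 0.68 ± 0.51 without passing (adjusted p = 0.285).

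Stress response genes were higher in the dual formulation than in LP PIC in 17 of 26 cases, with the endoplasmic reticulum chaperone-related gene Manf up by 1.08 (adjusted p = 1.49e-05, adjusted p = 0.196 with an estimated correlation). NRF2 genes were higher in 14 of 23 (adjusted p = 1.98e-05, adjusted p = 0.201 with an estimated correlation). Proliferation genes were higher in 17 of 40 cases (18 adjusted over the list alone; median 0.56, adjusted p = 0.00357, adjusted p = 0.718 with an estimated correlation and 0.0653 by fry), with Mki67, a marker of cycling cells, up by 1.17 ± 0.19 and Ccnd1 down by 1.03. Lysosome genes fell in 23 of 35 cases (25 adjusted over the list alone; median −0.54, adjusted p = 2.16e-05, adjusted p = 0.255 with an estimated correlation), Ctsb by 0.71 ± 0.10. LXR targets fell in 11 of 26 and rose in 2 (adjusted p = 0.014, adjusted p = 0.196 with an estimated correlation). Glycolysis genes rose in 13 of 25 and fell in 3 (adjusted p = 0.0185, adjusted p = 0.554 with an estimated correlation). Pattern recognition receptors rose in 13 of 35 and fell in 5 (adjusted p = 0.0277, adjusted p = 0.554 with an estimated correlation), a call lost without mouse 3 or 5 (adjusted p = 0.0756 and 0.0705). Neither comparison of the dual formulation with a single one kept a list call with an estimated correlation.

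The single formulations were compared directly to ask how they differ, and 5712 genes were called (2959 higher and 2753 lower in LP 3M than in LP PIC). Marco, a scavenger receptor gene, was higher in LP 3M by 7.05 ± 0.67 (2.45 to 329 CPM, adjusted p = 3.24e-07), Slc13a3, a dicarboxylate transporter gene, by 8.87 ± 0.92 (0.879 to 415 ± 304 CPM) and Lancl3 by 6.65 ± 0.68. Nhs and Raver2 were at least 218-fold and at least 219-fold higher, and Csf3 had a ratio of 567 (counting interval 102 to 22400). Tnf was higher by 1.92 ± 0.19, Il6 by 4.62 ± 0.81 and Il1b by 4.61 ± 0.87, whereas Il12b differed by 0.64 without passing (adjusted p = 0.444). Genes lower in LP 3M had log2 differences of −5.50 ± 0.49 for Cxcl10, −7.23 ± 0.93 for Ifit1bl1, −6.10 ± 0.83 for Gbp11 and −5.63 ± 0.60 for the Schlafen gene Slfn1. Krt16 and Cxcl11 were higher in LP PIC with ratios of 824 (228 to 6800) and 980 (176 to 38700), and Ifnb1 was at least 42.8-fold lower in LP 3M. Of 45 antiviral genes 44 were lower in LP 3M (median −1.60, adjusted p = 8.71e-16). So were 16 of 19 GTPases (adjusted p = 4.68e-08), 18 of 21 MHC class I genes (adjusted p = 2.05e-09) and 11 of 13 MHC class II genes (adjusted p = 0.000101). Each of these 4 lists had an adjusted p = 0.362 with an estimated correlation. Proliferation genes were higher in LP 3M in 39 of 40 cases (median 1.98, adjusted p = 2.05e-43, adjusted p = 0.132 with an estimated correlation), Bub1, a mitotic checkpoint gene, by 2.93. So were 18 of 25 cholesterol synthesis genes (median 0.57, adjusted p = 0.000252, adjusted p = 0.468 with an estimated correlation), Stard4 by 1.57. Glycolysis was higher in 16 of 25 (adjusted p = 0.000881, adjusted p = 0.362 with an estimated correlation) and NRF2 in 16 of 23 (adjusted p = 0.000798, adjusted p = 0.362 with an estimated correlation). The stress response was higher in 13 of 26 (adjusted p = 0.0035, adjusted p = 0.384 with an estimated correlation). Inflammasome genes were lower in 9 of 20 (adjusted p = 0.0409, adjusted p = 0.362 with an estimated correlation), a call lost without mouse 1, 2 or 4 (adjusted p = 0.0692, 0.0631 and 0.0843).

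The interaction asks whether the effects of the adjuvants on the log2 scale added up in the dual formulation. It was called for 1023 genes (463 above and 560 below the sum of the single changes; 1656 with mouse as a block). Called genes with the largest deviations below the sum included H2-M2 (−6.09 ± 0.63, adjusted p = 1.52e-05), Rasgrp1 (−5.22 ± 0.87), Bpifc (−4.98 ± 0.75) and Fpr2 (−4.95 ± 0.85). Those above it included Atp2b4 (4.68 ± 0.71, adjusted p = 0.000651) and Dusp2, a phosphatase that limits MAP kinases (3.99 ± 0.58, adjusted p = 0.000399). Irg1 (−3.33 ± 0.47, adjusted p = 0.000359), Sod2 (−2.35 ± 0.23) and Clec4e (−3.96 ± 0.40) rose with each single formulation and fell short of the log2 sum in the dual one. Classical activation enzymes were below the sum in 11 of 20 cases (median −1.71, adjusted p = 1.15e-13), the 1 of 12 list calls that held with an estimated correlation (adjusted p = 0.0483). NF-kB genes were below it in 10 of 30 and above it in 1 (15 and 2 adjusted over the list alone; median −0.54, adjusted p = 1.8e-08, adjusted p = 0.255 with an estimated correlation), with Relb at −1.22 ± 0.14. Proliferation genes were above the sum in 24 of 40 cases (30 adjusted over the list alone; median 1.16, adjusted p = 2.83e-23, adjusted p = 0.255 with an estimated correlation), with Mki67 at 1.94 ± 0.26 and Cdt1, a replication licensing factor gene, at 1.32 ± 0.18. Cholesterol synthesis (median −0.50, adjusted p = 3.43e-06) and oxidative phosphorylation (−0.28, adjusted p = 5.85e-06) were also below the sum, with an adjusted p = 0.379 each with an estimated correlation. So was lysosome (−0.30, adjusted p = 5.85e-06, adjusted p = 0.361 with an estimated correlation). The antiviral list did not pass (adjusted p = 0.115), except without mouse 3 (adjusted p = 0.0115; 0.0115 to 0.352 over the alternatives other than an estimated correlation and fry, which gave 0.663). Isg15 (−0.63 ± 0.72, adjusted p = 0.648), Il6 (0.07 ± 1.62, adjusted p = 0.989) and Il12b (2.67 ± 3.20, adjusted p = 0.664) were not called. Over the LP libraries Il6 and Il12b had 4 counts each, so their log2 sums are poorly determined and do not show additivity. Rasgrp1 and Fpr2 had 10 and 17 counts there. The count of calls moved widely with the mice included, at 182 without mouse 1, 291 without mouse 2, 702 without mouse 3, 242 without mouse 4 and 1398 without mouse 5. Among single left-out libraries it was 1804 without LP 3M PIC of mouse 5, 656 without that of mouse 1 and 665 without that of mouse 4. Fits chosen after the data had been seen gave 2161 calls in mice 1 and 2 alone and 69 in mice 3 to 5 alone. Lists whose median, mean and test differed in sign did not pass: NRF2 and the stress response in the dual formulation against LP 3M, antiviral genes, GTPases and alternative activation against LP PIC, LXR targets between the single formulations and NRF2 in the interaction (adjusted p from 0.167 to 0.881). By fry, alternative activation passed downward in the dual formulation against LP PIC (adjusted p = 0.0137).

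On the CPM scale, where additivity means that the dual level equals LP PIC plus LP 3M minus LP, 61 genes (cytokines, chemokines and the panel) were examined after their log2 values had been seen. In 5 of 5 mice 31 of them exceeded the sum and 5 stayed under it, and 25 went both ways. Il12b was at 353 CPM against a sum of 3.14, Il6 at 262 against 16.9, Il10 at 91.1 against 5.73, Il1b at 1055 against 133, Tnf at 990 against 485 and Cd40 at 248 against 72.6. Cd86 stood at 33.1 CPM against a sum of 58.5 and Csf1r at 1403 against 2196, and Ccl6, Ccl9 and Cxcl16 were also under the sum. Ifit1 lay near it, at 497 against 500.1. Irg1, Nos2 and Inhba were called below the sum of the log2 changes (−3.33, −5.05 and −3.00). The call for Nos2 was lost without mouse 1, 2 or 4 (adjusted p = 0.0913, 0.0527 and 0.0656) and that for Inhba without mouse 1 or 2 (adjusted p = 0.125 and 0.0849). On the CPM scale the 3 genes exceeded the sum in 5 of 5 mice, at 1794 against 1387, 249 against 112 and 139 against 69.0, so their direction turned with the scale. Sod2, Clec4e, Relb, H2-M2, Rasgrp1, Bpifc, Fpr2 and Saa3 were not examined on it, and the direction of some of them may turn as well. An exact two-sided sign-flip test was run for each gene, which with 5 mice gives no p under 0.0625 and so cannot pass 0.05, and no other test was run on this scale.

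The single responses overlapped. Of 12132 genes 1130 rose and 1209 fell with both single formulations, against 551 and 538 if the calls were independent, while 110 rose with LP PIC and fell with LP 3M and 197 did the reverse, against 538 and 550. Calls that share the LP libraries are not independent even without a change. In simulated unchanged groups against the same LP libraries, a mean of 0.1 genes was called in both comparisons by a likelihood-ratio test. The log2 changes correlated across genes at a Pearson coefficient of 0.573 and a Spearman coefficient of 0.482, but the LP libraries are shared and genes are not independent replicates. Simulated unchanged groups against the same LP libraries gave a Pearson coefficient of 0.501 with a covariance of 0.0322, against a covariance of 0.494 in the data. With the LP libraries split between the comparisons the Pearson coefficient was 0.408 to 0.582 and the covariance 0.304 to 0.404. The split values use differences of mean log2 CPM with a prior count of 2, which shrinks changes of low-count genes, and not the fitted changes. Their distance from the unsplit values therefore does not measure the effect of the shared LP libraries alone.

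Among markers of other cell types, those of neutrophils summed to 13.4 CPM in LP, 56.9 in LP PIC, 343 in LP 3M and 1519 in the dual formulation. In the order LP, LP PIC, LP 3M and dual, T cell markers were at 98.2, 60.4, 46.2 and 23.86 CPM, mostly through Cd28, which fell in the dual formulation, and B cell markers at 12.2, 11.5, 10.5 and 3.08. Cd28 was called lower with LP 3M too (adjusted p = 0.00697). It was also called with LP PIC (adjusted p = 0.0205), though not without mouse 4 (adjusted p = 0.0917). Of 5 tested T cell markers 3 rose and 1 fell with LP PIC, 2 fell with LP 3M, and 2 rose and 2 fell in the dual formulation. NK cell and erythroid markers stayed under 0.5 CPM in sum. In the same order, conventional dendritic cell markers were at 77.6, 31.7, 40 and 65.7 CPM. Itgax fell with LP PIC and the dual formulation and also with LP 3M (adjusted p = 0.0174), a call lost without mouse 1, 2 or 3 (adjusted p up to 0.0588), and Ccr7 and Fscn1 rose in the dual formulation. Ccr7 was also called higher with LP PIC (adjusted p = 0.000223). Plasmacytoid dendritic cell markers, mostly Tcf4, were at 54.6, 35.3, 40.5 and 44.4 CPM and mast cell and basophil markers at 0.606, 1.78, 0.609 and 8.07. Osteoclast markers summed to 425 CPM in LP, 432 in LP PIC, 529 in LP 3M and 616 in the dual formulation, where 3 of 8 tested members rose and 4 fell. Mmp9 rose there from 1.69 to 334 ± 438 CPM and Acp5 from 14.2 to 191, while Atp6v0d2 fell from 201 to 32.1. In the order LP, LP PIC, LP 3M and dual, stromal markers were at 61.5, 60.8, 69.9 and 81.2 CPM and endothelial markers, mostly Kdr, at 36.9, 70.5, 24.2 and 97.6. Megakaryocyte markers, mostly Pf4, were at 28.6, 25.2, 126 and 68.8 CPM in that order. Pf4 rose with LP 3M by 2.51 ± 0.73 (22.7 to 128.9 ± 140 CPM, adjusted p = 0.0107), a call lost without mouse 1 (adjusted p = 0.0857; 0.00217 to 0.0857 over the alternatives). With the dual formulation it was not called (adjusted p = 0.0544), but was by DESeq2 (adjusted p = 0.0439) and without mouse 3. Immediate early genes summed to 1322, 1070, 1007 and 1291 CPM in the same order. Of 12 tested, 6 fell and 1 rose with LP PIC, 5 fell and 1 rose with LP 3M, 3 fell and 2 rose in the dual formulation, and 5 were above the log2 sum in the interaction. Histone genes, with 1 tested member, summed to 37.6, 49.9, 38.4 and 50.1 CPM. The 13 listed mitochondrially encoded genes are not in the count tables.

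The genes behind the main results lie at these GRCm38 positions of GENCODE M21. Il12b is on chromosome 11 from 44400063 to 44414033, Il6 on chromosome 5 from 30013114 to 30019981, Nos2 on chromosome 11 from 78920787 to 78960254 and Tnf on chromosome 17 from 35199381 to 35202007. Il1b is on chromosome 2 from 129364570 to 129371139, Il10 on chromosome 1 from 131019845 to 131024974, Cxcl10 on chromosome 5 from 92346638 to 92348889 and Isg15 on chromosome 4 from 156199424 to 156200818. Ifnb1 is on chromosome 4 from 88522025 to 88522774, H2-M2 on chromosome 17 from 37480851 to 37483552, Fpr1 on chromosome 17 from 17876471 to 17883940 and Irg1 on chromosome 14 from 103046977 to 103056573. Cxcl11, on chromosome 5 from 92359544 to 92365485, is annotated as a polymorphic pseudogene.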

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

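Of the tests in this part, those of mixing, depth and animal for mouse 5, those of the neutrophil-type genes, and for proliferation those of composition and of counteraction by 3M, as well as the sign tests of the interaction and of the shared reads, were chosen after the result was seen.

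Among 110 groups of 5 libraries tested for a library far from the other 4, 6 stood out, where chance gives about 1 in 20, or 5.5. Cxcl9 in LP 3M of mouse 3 was at 0.7525 CPM against at most 0.140 in the other mice. In LP PIC, Il6 of mouse 5 was at 0.2281 CPM (0.648 to 0.799 in the others), Il12b of mouse 4 at 2.663 CPM (0.513 to 1.08) and Ciita of mouse 5 at 22.07 CPM (36.0 to 39.8). Depth was 17.36 M counts in LP PIC of mouse 5 (22.67 to 23.63 in the others) and 9.74 M in LP of mouse 2 (22.38 to 23.78).

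The effect of 3M differed with and without PIC, by the interaction term, in 1023 genes. Among named genes the log2 difference was 4.68 for Atp2b4, 4.61 for Il10, 3.99 for Dusp2, 3.67 for Sez6l2, 3.11 for Shisa9 and 3.05 for Htra4. It was −6.09 for H2-M2, −5.22 for Rasgrp1, −5.05 for Nos2, −4.98 for Bpifc, −4.95 for Fpr2, −4.54 for Saa3, −3.33 for Irg1, −1.34 for Cd86 and −0.65 for Csf1r. Several of these calls were lost when a mouse was left out. The highest adjusted p was 0.158 for Il10 and 0.126 for Saa3, 0.0913 for Nos2, 0.103 for Cd86 and 0.0982 for Csf1r, each without mouse 1. It was 0.0656 for Sez6l2, 0.0674 for Shisa9 and 0.127 for Htra4, also without mouse 1. Over the alternatives their lowest adjusted p lay between 1.54e-05 and 0.000712.

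When condition labels were permuted within mice, 2 of 40 permutations, the real one included, gave as many interaction calls as the real 1023, and the highest other gave 1604. Chance was therefore not excluded by this test, in which permuted labels carry the main effects into the contrast. When the sign of the interaction was flipped in whole mice, 1 of 16 patterns, the real one, was as large as the real count. By limma, 1192 genes were called for the real signs, and the highest other pattern gave 0. For the real signs edgeR called 1023 genes, and 2884 at an unadjusted p under 0.05. With 16 patterns the share cannot be under 0.0625.

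In an entry that the comparisons do not use, 1.75% of the reads in LP PIC were assigned to more than 1 gene, against 1.14 to 1.34% in LP. The share was higher than in LP in 5 of 5 mice (exact two-sided sign-flip permutation test, n = 5 mice, p = 0.0625, the smallest that 5 mice can give). It was 1.53% in LP 3M PIC, higher in 5 of 5 mice (exact p = 0.0625), and 1.26% in LP 3M, higher in 4 of 5 (exact p = 0.625).

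LP 3M of mouse 5 responded less than the other LP 3M libraries. Of the 2422 genes called higher with LP 3M, 192 with a large rise and a mean of at least 5 CPM there were used. Over these its median response was 0.368 of the mean of the other mice. Il1b was at 3.59 CPM against 73.5 to 328, while Tnf, at 308 CPM, lay within the 283 to 550 of the others. Mixing with RNA of LP cells would shrink every gene alike, but the ratio of the 90th to the 10th percentile of the response was 9.87 against at most 4.39 in another mouse. This argues against mixing alone, if mouse 5 otherwise had the spread of the other mice. Mixing on top of a difference of the animal cannot be decided by it. Depth, at 22.94 M counts, was not the lowest of the condition. A property of the cells of mouse 5 is a candidate explanation, since that mouse ranked 1 (lowest of 5) in median response in both LP PIC and LP 3M PIC. Its responses, each over genes picked by the same rule for that condition, were 0.522 over 207 genes in LP PIC (next 0.608 in mouse 3). In LP 3M PIC the response was 0.641 over 432 genes (next 0.925 in mouse 3). These share its LP library, but without LP subtracted it was lowest too, at 0.553 (next 0.706) and 0.673 (next 0.983), and handling of its cultures was not tested and stays open.

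S100a8 and Lcn2, abundant in neutrophils, summed to 5.61 CPM in LP and 1470 in LP 3M PIC. Neutrophils in the cultures would bring their other abundant transcripts, but the other 12 neutrophil markers summed to 47.4 CPM in LP 3M PIC, of which Mmp8 held 45.5, and S100a9 was at 0.106. Induction in the macrophages may account for the rise, since the sum of the 2 genes was highest in LP 3M PIC in 5 of 5 mice. That sum was mostly Lcn2 (1340 CPM, against 133 for S100a8). The ranking holds for any effect of the dual formulation and cannot be told apart here from another source.

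Proliferation genes fell less with the dual formulation than the single log2 changes add up to, with list medians of −2.66 for LP PIC, −0.57 for LP 3M, −2.18 for the dual one and 1.16 for the interaction. An expression floor is argued against by 34 of the 40 genes, which stayed above 10 times the floor of 0.308 CPM in their lowest condition. A minority of the mice alone is argued against by list medians above 0 in 5 of 5 mice (2.09, 1.42, 0.52, 1.15 and 0.03), although mouse 5 is close to 0. Composition or scaling stays open, because scaling sets the median interaction of all tested genes near 0 (0.001) and no value decides whether all genes shifted. Counteraction of the PIC effect on cycling by 3M also stays open, with 17 of the 40 genes higher in LP 3M PIC than in LP PIC, as does a limit to how far cycling falls.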

How the results depend on the processing

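The fits to mice 1 and 2 and to mice 3 to 5 alone and the fit without the 2 shallowest libraries were chosen after the data had been seen. The interaction depended most on the processing: against 1023 calls, mouse as a block gave 1656, mice 1 and 2 alone 2161, mice 3 to 5 alone 69 and the fit without the 2 shallowest libraries 665, and leaving out libraries or mice gave 182 to 1804. Mice 3 to 5 alone gave 2795 calls for LP 3M against LP and 3237 for LP 3M PIC against LP PIC, where mice 1 and 2 alone gave 4631 and 5352. The cause of these shifts was not tested, and these groups of mice also differ in Xist and Y-linked transcripts. The calls of the 6 comparisons between 2 conditions otherwise stayed within 1.5 times their counts. Leaving out libraries or mice gave 4195 to 5351 for LP PIC against LP, 3523 to 5148 for LP 3M against LP and 6740 to 7685 for LP 3M PIC against LP. It gave 3844 to 5261 for LP 3M PIC against LP 3M, 4035 to 5927 for LP 3M PIC against LP PIC and 4209 to 5764 for LP 3M against LP PIC. With an estimated correlation camera called 4 lists for LP PIC against LP, 2 for LP 3M against LP, 2 for LP 3M PIC against LP and 1 for the interaction, against 13, 15, 18 and 12 at the preset correlation. It called 0 lists for LP 3M PIC against LP 3M, LP 3M PIC against LP PIC and LP 3M against LP PIC, where camera called 15, 11 and 10 at the preset correlation and fry 17, 12 and 12, and where 6, 5 and 1 lists had an unadjusted p under 0.05 with the estimated correlation. For 18 to 21 of the 21 lists of a comparison, the estimated correlation gave the highest adjusted p of all alternatives. Named genes were followed under the block, median-ratio size factors, no filter, DESeq2 and each left-out mouse, and not in the other fits. Among 766 results, 0 reversed direction with a call in the main fit or the alternative. Changes of sign where neither fit gave a call were not counted. The block gained 29 calls and lost 3, DESeq2 gained 9 and lost 1, no filter lost 22 and median-ratio size factors lost 1. Of the left-out mice, mouse 1 cost 66 calls, mouse 2 52, mouse 3 25, mouse 4 66 and mouse 5 6. Calls gained were 9 without mouse 3, 4 without mouse 5 and 1 each without mouse 2 and without mouse 4. Of 147 list results the block gained 5, and apart from the values given with each result it changed no other call named in the text. The correlation of the single responses was 0.408 to 0.582 with the LP libraries split, taken from mean log2 CPM and not from fitted changes. Depth limits low-expressed genes most in LP of mouse 2, where 3 counts are 0.308 CPM.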

Other observations

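The genes of the first paragraph were picked after their values had been seen, and so were the fits by groups of mice in the second. Some cytoskeleton genes moved in opposite directions with the single formulations. The genes named in this paragraph were called in both comparisons with LP, but their direction in each mouse was not checked here. The tubulin genes Tubb5, Tuba1c and Tubb4b fell with LP PIC (log2 changes −1.35, −0.99 and −1.13) and rose with LP 3M (0.73, 0.76 and 0.48), and so did the actin genes Actb (−0.71 and 0.80) and Actg1 (−0.54 and 0.84). Flna, which cross-links actin filaments (−0.86 and 0.72), Cnn2, an actin-binding calponin gene (−1.60 and 0.90), and Coro1a, a coronin gene of leukocytes (−0.49 and 1.13), did the same. With the dual formulation most of these lay near LP, at 0.08 for Tubb5, −0.12 for Flna and 0.27 for Cnn2, while Coro1a stayed high at 1.18. Among cytokine genes Il18 rose with LP PIC (0.74) and fell with LP 3M (−1.21), and Ccl7 did the reverse (−1.48 and 2.77). No gene list for the cytoskeleton was fixed, so these are examples and not a test of the group.

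Xist, the transcript of the inactive X chromosome, was at 300.2 to 622.3 CPM in the 8 libraries of mice 1 and 2 and at most 0.176 CPM in the 12 libraries of mice 3 to 5. The Y-linked Ddx3y was at 27.4 to 53.1 CPM in mice 3 to 5 and had no counts in mice 1 and 2. The labels used here give no sex, but these transcripts mark mice 1 and 2 as female and mice 3 to 5 as male. No fit had a term for sex, although mouse as a block also takes up such differences. The fits by groups of mice therefore also split the sexes. Of the genes called with all 5 mice, 99.1 to 100% per comparison had the same sign in mice 1 and 2 alone as in mice 3 to 5 alone, where the calls came from the same libraries.

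Other assignments of the same libraries were compared with the real one for each count of calls, 40 splits per comparison. In each of the 6 comparisons between 2 conditions, 1 of 40 splits, the real one, gave as many calls. Of the 40 splits 16 part every pair of libraries from the same mouse, as the real one does, and the real one was alone among these too, but 16 splits cannot give a share under 0.0625. The real counts and the highest of the other splits were 5515 and 1245 for LP PIC against LP, 4790 and 2121 for LP 3M against LP, and 7551 and 3059 for LP 3M PIC against LP. They were 5032 and 1616 for LP 3M PIC against LP 3M, 5397 and 3324 for LP 3M PIC against LP PIC, and 5712 and 1302 for LP 3M against LP PIC. Among the 16 splits the highest other counts were 1245, 815, 2475, 1, 1765 and 1302 in that order.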
